A study of Homo sapiens with 24 samples.

How the data were processed

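Gene expression was measured by RNA sequencing in the human neuroblastoma lines SK-N-SH and SK-N-AS after knockdown of FAM167A. RNA was extracted with TRIzol and cleaned on RNeasy columns. The CRISPRi libraries were made with the Illumina Stranded mRNA Prep kit, and the siRNA libraries from mRNA isolated on poly-T beads, with a protocol that covers both a stranded and a non-stranded kit. Per the labels, the authors' processing used bcl2fastq 2.20.0.422 and 2.20, CASAVA (version not given in the sources used here), FastQC 0.11.8, STAR 2.6.1d and featureCounts 1.5.1 on GRCh38; which of these served which experiment is not given there. The deposited tables hold counts, as raw reads per gene with a column per library, 1 table for each of the 3 experiments. The values were whole numbers with a different total in each library, and all 24 libraries were used. The annotation release and the strand setting of the counting are not given in the sources used here. The tables list 58735 genes for SK-N-SH siRNA, 61541 for SK-N-SH CRISPRi and 78932 for SK-N-AS CRISPRi, of which 58207, 61369 and 61481 have a symbol in the table.

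Each experiment was analysed alone, knockdown against its own non-targeting controls (5 against 5, 3 against 3 and 4 against 4 libraries), in R 4.3.3. Genes were kept by edgeR's filterByExpr (edgeR 4.0.16; minimum count 10, minimum total 15), which left 21018, 15391 and 19277 genes, of which 18237, 14443 and 16165 have a symbol. Counts were scaled by TMM factors, dispersions were estimated across genes, and edgeR's quasi-likelihood test (glmQLFit with robust set to true, glmQLFTest) gave two-sided p-values, adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05 with no fold threshold, and counts at least 2-fold (log2 fold change of at least 1 in size) are given beside it. The standard error of a log2 fold change was taken from the estimate and the test statistic. The median log2 fold change over all tested genes was 0.0085, -0.0068 and -0.0024. Unadjusted p-values under 0.05 numbered 4567, 9174 and 7549.

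Gene lists, comparisons, tests, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise. There were 29 pathway lists, of which 1 is not reported here, nor are some genes that the rule below selects. The others were the actomyosin cytoskeleton, actin nucleation and protrusion, integrins and focal adhesion, collagens, matrix glycoproteins and proteases, YAP and TAZ targets, immediate early genes, TGF-beta targets, adrenergic and mesenchymal neuroblastoma identity, neurite and neuronal differentiation, axon guidance, cadherins and protocadherins, DNA replication, mitosis, p53 targets, interferon response, antigen presentation, NF-kB and inflammatory mediators, sterol synthesis, integrated stress and unfolded protein response, heat shock, hypoxia and glycolysis, nuclear and mitochondrially encoded oxidative phosphorylation genes, cytosolic ribosomal proteins, lysosome and autophagy, and FAM167A with its 8p23.1 neighbours. A further 5 lists held markers of other cell types: Schwann cell precursors and glia, epithelial, endothelial and blood cells, and fibroblasts and smooth muscle cells. All 878 list genes were found in each table by symbol. Lists with at least 5 tested members were tested with camera (limma 3.58.1), two-sided, with a correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry, which asks whether a list's genes move on balance without comparing them with other genes, were run beside it. Members passing were counted after adjustment over all genes and over the list alone.

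The genes named are FAM167A, FAM167B, FAM167A-AS1, BLK and the MRCK genes; in each experiment the 8 largest rises and 8 largest falls among changed genes with a mean of at least 1 log2 CPM, every knockdown library on one side of every control library and a symbol; up to 4 changed members of each list with the smallest adjusted p, or 2 where none changed; up to 15 genes called in one direction in all 3 experiments; and up to 8 genes per test of a difference between experiments. Other genes named were chosen after their values were seen, and this is said where they appear.

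Calls shared between experiments were counted among genes tested in both and set against the product of the list sizes over the number of genes. The correlation r is Pearson's over log2 fold changes across genes, with Spearman's rho beside it. Differences in response between the SK-N-SH experiments, and between the CRISPRi experiments, were tested as an interaction in an edgeR model over both experiments, with each experiment's own controls. This model holds a single spread per gene for both experiments, and its genes were filtered over both together. The siRNA and SK-N-AS CRISPRi experiments differ in both line and method, so that difference was not tested. Camera on the interaction was added after the data were seen.

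Alternatives were size factors by the RLE method, DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM, replicate number as a block, each library left out in turn, a fold threshold, camera with an estimated correlation, fry and Spearman's rho; added after the data were seen were leaving out knockdown library 4 and control library 5 of the siRNA experiment together, and separate fits for the differences between experiments. Replicate numbers were not used as pairs, since residuals of knockdown and control libraries of equal number correlated at -0.14 to 0.048 with siRNA, -0.02 to 0.025 in SK-N-SH CRISPRi and -0.033 to 0.0047 in SK-N-AS CRISPRi. Results were recomputed on other splits of the libraries into groups of the same sizes, all of them or 100 drawn at random (50 for differences between experiments). Whether replicates are separate cultures is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

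In siRNA libraries, matches to a small RNA's seed were sought as heptamers of 7 bases in annotated 3′ untranslated regions of genes with a mean of at least 1 log2 CPM. Each heptamer present in at least 50 genes was scored by the t statistic of its presence in a regression of log2 fold changes, limited to 2 in size. The length and GC content of the 3′ untranslated region and the mean expression were removed first. Regions were found for 98.5% of such coding genes in each experiment. A fold against a group without reads is a lower bound from a floor of 3 counts over the group, a fold against 1 to 3 reads is given as a ratio with its 95% interval, and floors and intervals cover counting error only.

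The steps were tested on simulated counts made from each experiment's own libraries with 200 genes changed. Of 50 genes changed 2-fold each, 80, 90 and 84% were called in the siRNA, SK-N-SH CRISPRi and SK-N-AS CRISPRi settings. Of 50 changed 1.5-fold 68, 80 and 56% were called, and of 50 changed 1.25-fold 50, 62 and 66%. The SK-N-AS share was lower for 1.5-fold than for 1.25-fold, so these shares are rough. Of unchanged genes 10, 19 and 6 were called. The simulation changed far fewer genes than were called here and drew independent noise for each gene, so its shares need not hold for the data. Further scripts used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.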

Results

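RNA sequencing was used to measure gene expression after knockdown of FAM167A (also called DIORA1), a gene at chromosome 8p23.1, in human neuroblastoma cell lines. The study concerns binding of this protein to the MRCK kinases, which phosphorylate myosin light chain regulators downstream of CDC42, and its part in cell movement. SK-N-SH is a line that holds both neuroblast-like and flat, substrate-adherent cells, and SK-N-AS is a second neuroblastoma line. In the SK-N-SH siRNA experiment a pool of small interfering RNAs against FAM167A (5 libraries) was compared with a non-targeting pool (5 libraries). In the CRISPRi experiments a catalytically inactive Cas9 fused to the KRAB repressor was guided to the gene, or to the yeast Gal4 site as control, in SK-N-SH (3 against 3 libraries) and in SK-N-AS (4 against 4 libraries). Each experiment had its own controls, and the 24 libraries fall into 6 groups. Reads assigned to genes per library ranged from 71464698 to 90255175 in the siRNA experiment, from 11690515 to 21628076 in SK-N-SH CRISPRi and from 29985858 to 104455853 in SK-N-AS CRISPRi. Levels are in CPM, counts normalised to a common library size, as mean ± SD over the libraries of a group, and log2 fold changes are knockdown over control ± standard error (SE). A gene rose or fell where its Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test lay under 0.05. A list of genes rose or fell where camera, which tests whether its members moved relative to all other genes, gave an adjusted p under 0.05. Splits that mix knockdown and control libraries and call no gene still called up to 20 lists with siRNA by this test. Such splits called up to 21 lists in SK-N-SH CRISPRi and up to 19 in SK-N-AS CRISPRi. A call with the preset correlation alone therefore does not tell an effect of knockdown from differences between single libraries.

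FAM167A (ENSG00000154319; GRCh38 chromosome 8, 11421476 to 11475908, minus strand) fell in all 3 experiments. With siRNA it dropped from 188 ± 12.5 to 65.2 ± 5.13 CPM (n = 5 in each group), 2.88-fold, which left 34.7% of the control level (log2 fold change -1.53 ± 0.055, adjusted p = 7.87e-14). CRISPRi in SK-N-SH took it from 242 ± 12.7 to 3.22 ± 0.588 CPM (n = 3 in each group), 75.3-fold, or 1.33% of control (log2 fold change -6.23 ± 0.08, adjusted p = 1.82e-37). CRISPRi in SK-N-AS took it from 95.1 ± 3.56 to 10.2 ± 0.739 CPM (n = 4 in each group), 9.32-fold, or 10.7% of control (log2 fold change -3.22 ± 0.05, adjusted p = 2.9e-33). The fall was larger with CRISPRi than with siRNA in SK-N-SH by 4.72 ± 0.13 on the log2 scale (adjusted p of the difference 2.2e-22). In each experiment every knockdown library lay below every control library. The paralogue FAM167B did not pass the test with siRNA (log2 fold change 0.24 ± 0.28, adjusted p = 0.683) or in SK-N-AS (-0.57 ± 0.49, adjusted p = 0.42). Its 17 knockdown against 29 control reads in SK-N-SH CRISPRi were too few to be tested. The antisense gene FAM167A-AS1, which overlaps the last part of FAM167A, rose in SK-N-AS CRISPRi (297 against 75 reads, log2 fold change 1.73 ± 0.33, adjusted p = 6.83e-05) and did not pass with siRNA (0.13 ± 0.27, adjusted p = 0.838). The strand setting of the read counting is not given in the sources used here, so the origin of reads assigned to antisense genes is uncertain. The neighbouring kinase gene BLK fell in SK-N-SH CRISPRi (12 against 52 reads, log2 fold change -1.96 ± 0.43, adjusted p = 0.000129), did not pass with siRNA (0.00 ± 0.14, adjusted p = 0.994) and was too low to be tested in SK-N-AS.

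**Figure D1:**
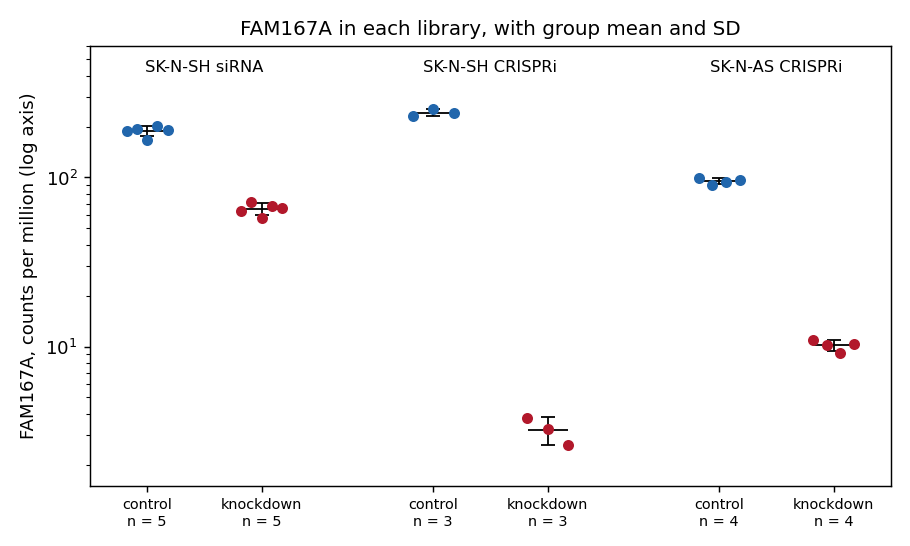
FAM167A in normalised counts (CPM) on a log axis, a point per library, with the mean and SD of each group, in the 3 experiments. Knockdown libraries lay between 57.67 and 71.39 with siRNA, between 2.619 and 3.793 with CRISPRi in SK-N-SH and between 9.169 and 10.95 with CRISPRi in SK-N-AS, all below their controls.

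The siRNA experiment asks which genes change when FAM167A mRNA is lowered in SK-N-SH. NF-kB and inflammatory mediators fell as a list, 15 of 22 down (adjusted p = 1.71e-13, adjusted p = 0.18 with an estimated correlation). CXCL8, the neutrophil chemoattractant interleukin-8, fell 9.49-fold from 16.4 ± 7.7 to 1.71 ± 0.515 CPM (n = 5 in each group, adjusted p = 0.000603). MMP1, an interstitial collagenase, fell 5.31-fold, PLAU, the urokinase-type plasminogen activator, 4.1-fold, ITGA2, the collagen-binding integrin alpha 2 chain, 3.57-fold, and CD44, the hyaluronan receptor, 3.26-fold. Among the genes that rose at least 2-fold were CXCL12, the ligand of the chemokine receptor CXCR4, 3-fold, and KLF2, a transcription factor of quiescent endothelium and T cells, 2.38-fold. Of 21018 genes tested, 2004 (9.53%) changed, 536 upward and 1468 downward, and 147 of them at least 2-fold, 18 upward and 129 downward. The 536 rises were 331 without knockdown library 3, 345, 297 and 282 without control library 1, 2 or 4, 322 with a replicate block and 813 by DESeq2.

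The other leading falls were CA12, a membrane carbonic anhydrase (log2 fold change -2.30 ± 0.06), ANO3 (-1.80 ± 0.16), the long non-coding RNA LINC00702 (-1.77 ± 0.14) and MEGF10, an engulfment receptor (-1.77 ± 0.16). The other leading rises were PRR15 (1.13 ± 0.13), the carboxypeptidase gene CPA4 (0.96 ± 0.06), the imprinted gene MEST (0.94 ± 0.07), the bone morphogenetic protein gene GDF6 (0.91 ± 0.13), GFRA1, a co-receptor for GDNF (0.86 ± 0.15), and the microRNA host locus MIR503 (0.85 ± 0.14).

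Adhesion and matrix lists fell with siRNA. Of 42 tested matrix glycoproteins and matrix proteases 18 fell and 4 rose (adjusted p = 3.47e-25). THBS2, a thrombospondin, stood at -0.89 ± 0.05 and PLAT, the tissue plasminogen activator, at -0.81 ± 0.05. Of 30 integrin and focal adhesion genes 10 fell and 1 rose (adjusted p = 1.67e-11). ITGA6 stood at -0.87 ± 0.07, ITGA5 at -0.71 ± 0.06 and ITGB3 at -0.69 ± 0.08. With an estimated correlation between genes neither list kept its call (adjusted p = 0.11 for each). Of 18 collagens 6 fell and 2 rose (adjusted p = 0.00316, adjusted p = 0.46 with an estimated correlation). Without genes that hold either of 2 seed heptamers in their 3′ untranslated region, a choice made after the data were seen, the collagens were not called (adjusted p = 0.0572, median 0.06). COL6A3 stood at -1.02 ± 0.07, COL13A1 at -0.95 ± 0.09 and COL8A1 at -0.55 ± 0.05. Of 27 genes of actin nucleation and protrusion 4 fell and 1 rose (adjusted p = 0.0118, adjusted p = 0.24 with an estimated correlation). Among them MYO10, a filopodial myosin, stood at -0.34 ± 0.05 and VASP, an actin polymerase, at -0.27 ± 0.05, while ENAH rose (0.17 ± 0.04). In the SK-N-SH siRNA experiment this list lost its call under a filter at 1 CPM (adjusted p = 0.0596). The actomyosin cytoskeleton list, 3 of 28 up and 2 down, did not move as a set (adjusted p = 0.77), with TAGLN at 0.63 ± 0.06, TPM1 at 0.23 ± 0.04 and ACTA2 at -0.35 ± 0.07. MYLK, the myosin light chain kinase, fell (-0.35 ± 0.05), as did LIMK1 (-0.30 ± 0.04). The MRCK genes themselves did not pass: CDC42BPA stood at -0.05 ± 0.04 (adjusted p = 0.553), CDC42BPB at -0.02 ± 0.05 (adjusted p = 0.83) and CDC42BPG at 0.03 ± 0.07 (adjusted p = 0.889).

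Of 28 mesenchymal neuroblastoma identity genes 13 fell and none rose (adjusted p = 1.81e-23, adjusted p = 0.11 with an estimated correlation). They include SOX9 at -1.25 ± 0.06, BHLHE41 at -0.79 ± 0.07 and WWTR1, which encodes the coactivator TAZ, at -0.62 ± 0.06. Of 25 adrenergic identity genes 4 rose and 1 fell (adjusted p = 0.00729, adjusted p = 0.42 with an estimated correlation). The receptor tyrosine kinase RET stood at 0.31 ± 0.04. Of 21 YAP and TAZ targets 7 fell and 3 rose (adjusted p = 0.00494, adjusted p = 0.46 with an estimated correlation). IGFBP3 fell (-1.09 ± 0.06), NT5E fell (-0.91 ± 0.06), and ANKRD1 and CCDC80 rose (0.47 ± 0.06 and 0.24 ± 0.04). Without knockdown library 1 this list was no longer called (adjusted p = 0.123). Of 19 TGF-beta targets 3 fell, among them CDKN2B and TGFB1 (-0.74 ± 0.06; list adjusted p = 0.00729, adjusted p = 0.43 with an estimated correlation). Of 36 axon guidance genes 10 fell and 4 rose (adjusted p = 3.35e-05, adjusted p = 0.24 with an estimated correlation). The semaphorin co-receptor NRP1 stood at -0.94 ± 0.04 and SEMA3D at -0.84 ± 0.05. Neurite genes (1 up and 3 down of 28, adjusted p = 0.893) and cadherins (1 up and 5 down of 20, adjusted p = 0.0646) were not called as lists. SCG2, a granin of secretory granules, fell (-0.62 ± 0.05), as did CDH18 (-1.26 ± 0.11) and N-cadherin, CDH2 (-0.47 ± 0.04). Without knockdown library 2, 3 or 4 of the SK-N-SH siRNA experiment the cadherin list passed (adjusted p = 0.0443, 0.0263 and 0.0475).

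NF-kB and inflammatory mediators had the lowest median of the called lists, -0.57, with 15 of 22 down and 1, CXCL12, up (adjusted p = 1.71e-13, adjusted p = 0.18 with an estimated correlation). LIF fell (-0.91 ± 0.11), as did the cytokine genes IL11 (-0.80 ± 0.10) and CSF1 (-0.64 ± 0.06). Of 28 p53 targets 19 fell and none rose (adjusted p = 7.98e-18, adjusted p = 0.11 with an estimated correlation). The antiproliferative gene BTG2 stood at -1.20 ± 0.05 and the stress cytokine gene GDF15 at -1.07 ± 0.08. Of 28 lysosome and autophagy genes 17 fell and none rose (adjusted p = 1.67e-11, adjusted p = 0.15 with an estimated correlation). The protease gene CTSB stood at -0.57 ± 0.06 and the autophagy receptor gene SQSTM1 at -0.48 ± 0.06. Immediate early genes fell (6 down and 2 up of 23, median -0.12, adjusted p = 0.000141), with KLF6 at -0.40 ± 0.05 and NR4A2 at -1.32 ± 0.22. Without genes that hold a seed heptamer the 16 left were not called (adjusted p = 0.111), although their median, -0.13, was no smaller in size. Stress and unfolded protein response genes fell (9 of 31 down, adjusted p = 0.00012), with EDEM1 at -0.51 ± 0.05 and CRELD2 at -0.54 ± 0.05. Hypoxia and glycolysis genes fell (7 of 34 down, adjusted p = 0.00101), with the glucose transporter gene SLC2A3 at -0.69 ± 0.06. Antigen presentation genes fell (5 of 19 down, adjusted p = 0.00185), with the peptide transporter gene TAP1 at -0.47 ± 0.07. With an estimated correlation these last 4 lists had adjusted p = 0.2, 0.34, 0.42 and 0.26 in the order given.

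Mitosis genes rose (6 of 32 up, adjusted p = 0.000647, adjusted p = 0.42 with an estimated correlation), by small amounts such as 0.23 ± 0.05 for CENPF, a kinetochore protein, and 0.17 ± 0.04 for the spindle motor gene KIF11. DNA replication genes were not called (adjusted p = 0.0839; 0.0475 without knockdown library 4). Of 30 only MCM10 rose, and its call was lost without control library 2 (adjusted p = 0.0652) or 4 (0.0507). The 13 mitochondrially encoded genes were called lower as a list (adjusted p = 0.00316, adjusted p = 0.5 with an estimated correlation) although none passed on its own. Mitochondrial genes took 6.45 and 6.41% of reads in knockdown libraries 3 and 4, 8.45 to 8.67% in the other knockdown libraries and 7.83 to 9.07% in controls. The call was lost without knockdown library 4 and control library 5, which stand apart from their groups (adjusted p = 0.0766). In these libraries the median of ribosomal protein genes lay -0.24 and -0.23 (log2) from that of the others of their group, and the 48 cytosolic ribosomal proteins, none of them called, had an adjusted list p of 0.0583. That p fell to 0.000646, 0.000347 and 0.000748 without knockdown library 1, knockdown library 5 or control library 5 of the SK-N-SH siRNA experiment. Nuclear oxidative phosphorylation genes (0 of 38 called, adjusted p = 0.783), sterol synthesis (1 up and 1 down of 26, adjusted p = 0.674), heat shock (1 up and 2 down of 19, adjusted p = 0.971) and interferon response (2 up and 1 down of 37, adjusted p = 0.643) were not called. The list of FAM167A and its 8p23.1 neighbours passed only with the target among its members (adjusted p = 0.0087, adjusted p = 0.11 with an estimated correlation). Without FAM167A, left out here and below after the data were seen, the other 17 genes, CTSB and NEIL2 down, had an adjusted p of 0.83. Of the 5 cell type lists none was called: Schwann cell precursor and glia (adjusted p = 0.737), epithelial (0.814), endothelial (0.0603), blood (0.971) and fibroblast and smooth muscle cells (0.0839). The endothelial list passed without knockdown library 4 (0.0475), control library 1 (0.0452) or control library 2 (0.046), and the fibroblast list without control library 2 (0.0461).

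Adjusted over the list alone, 267 list members passed in place of 221 adjusted over all genes (a gene counts in each of its lists), and the counts were equal in 16 of the 34 lists; the actomyosin list then had 6 up and 6 down, the mesenchymal list 1 up and 18 down, and integrins 1 up and 14 down. Median, mean and test differed in sign for neurite genes (0.04, -0.01, lower), cadherins (0.02, -0.16, lower), actomyosin (-0.04, 0, higher), interferon response (0.04, -0.02, higher), heat shock (0, -0.01, higher), Schwann cell markers (-0.07, 0.05, lower), epithelial markers (-0.07, 0.02, higher) and blood markers (-0.04, -0.12, higher), none of them called. In all 19 of 34 lists were called by camera with siRNA, 2 up and 17 down, and 0 with an estimated correlation (20 by fry). Other splits of the same libraries called up to 20 lists. Without genes that hold a seed heptamer, cadherins (adjusted p = 0.0051), DNA replication genes (0.0278) and ribosomal proteins (0.0141) were called, and these calls were lost with an estimated correlation (adjusted p = 0.18, 0.35 and 0.77). Without both libraries that stand apart, left out after the data were seen, 2204 genes changed, of which 1751 were among the 2004.

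The SK-N-SH CRISPRi experiment asks the same question in a line of the same name with a deeper loss of FAM167A. Adrenergic genes fell, 23 of 25, and collagens rose, 14 of 17, as lists (adjusted p = 1.07e-56 and 1.91e-21). Both calls were lost with an estimated correlation (adjusted p = 0.059 and 0.082). DCX, a microtubule protein of migrating neurons, fell 9.05-fold from 46.1 ± 5.69 to 5.07 ± 0.612 CPM (n = 3 in each group, adjusted p = 9.59e-22), and RET fell 4.67-fold from 348 ± 7.74 to 74.4 ± 3.11 CPM. COL3A1, the chain of type III collagen, rose 2.85-fold from 1445 ± 43.9 to 4120 ± 41.8 CPM, and BGN, the matrix proteoglycan biglycan, rose 7.78-fold from 6.42 ± 0.228 to 49.8 ± 2.07 CPM. Of 15391 genes tested, 8582 (55.8%) changed, 4269 upward and 4313 downward, and 1658 of them at least 2-fold, 449 upward and 1209 downward. TMM scaling takes most genes as unchanged, so the balance of rises and falls, and small shifts of genes and lists, depend on it here. The TMM factors were 0.9538 to 0.9578 in knockdown and 1.037 to 1.051 in control libraries.

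TEAD3, a DNA-binding partner of YAP and TAZ, left 2 reads in the knockdown libraries against 782 in the controls, a ratio of 358 (95% counting interval 98.9 to 2960). CD63-AS1 had no reads in knockdown and 190 in control, at least 58-fold lower with a floor of 3 counts over the group. The other leading falls after FAM167A were SILC1 (-4.97 ± 0.46), SERTM2 (-4.33 ± 0.30), LAMP5, a lysosome-associated membrane protein of neurons (-3.53 ± 0.18), and NMU, the peptide neuromedin U (-3.34 ± 0.24). The leading rises were NECTIN3-AS1 (4.78 ± 0.19), the skeletal muscle myosin heavy chains MYH1 (4.31 ± 0.32) and MYH2 (4.22 ± 0.34), the complement regulator CD55 (4.04 ± 0.28), the lipid kinase PIK3C2G (3.97 ± 0.22), the microfibril protein MFAP5 (3.74 ± 0.05), the glutamate receptor subunit GRIA1 (3.50 ± 0.17) and FAM9C (3.33 ± 0.11).

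Of 25 adrenergic identity genes 23 fell and 1 rose, with a median of -1.66 (adjusted p = 1.07e-56, adjusted p = 0.059 with an estimated correlation). The transcription factor GATA2 stood at -2.08 ± 0.04, DLK1 at -1.91 ± 0.04 and DBH, the enzyme that makes noradrenaline, at -1.62 ± 0.04. Of 27 neurite and neuronal differentiation genes 22 fell and 4 rose, with a median of -1.75 (adjusted p = 1.27e-26, adjusted p = 0.082 with an estimated correlation). The adhesion molecules L1CAM (-1.86 ± 0.05) and CNTN1 (-2.63 ± 0.09) and the RNA-binding protein gene ELAVL3 (-1.91 ± 0.06) fell. Of 28 mesenchymal identity genes 22 rose and 3 fell, with a median of 0.63 (adjusted p = 5.5e-10, adjusted p = 0.14 with an estimated correlation). The homeobox gene PRRX1 (1.21 ± 0.04) rose, as did YAP1 (0.76 ± 0.04). Axon guidance genes went both ways, 17 up and 11 down of 34, with a median of 0.14, a mean of -0.18 and no call (adjusted p = 0.564). The netrin receptor UNC5B fell (-1.75 ± 0.04) and SLIT2 rose (0.92 ± 0.04).

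Of 17 collagens 14 rose and 1 fell, with a median of 1.04 (adjusted p = 1.91e-21, adjusted p = 0.082 with an estimated correlation). COL5A1 (1.29 ± 0.04), COL4A1 (1.14 ± 0.04) and COL4A2 (1.02 ± 0.04) rose. Of 40 matrix glycoproteins and proteases 33 rose and 7 fell (adjusted p = 1.57e-21, adjusted p = 0.1 with an estimated correlation). PLAT stood at 1.78 ± 0.04 and the matricellular protein periostin, POSTN, at 1.21 ± 0.04. Of 29 integrin and focal adhesion genes 23 rose and 5 fell (adjusted p = 2.79e-13, adjusted p = 0.082 with an estimated correlation). ITGA10 stood at 2.27 ± 0.08, ITGA2 at 1.27 ± 0.04 and vinculin, VCL, at 0.98 ± 0.04, while ITGA9 fell (-2.51 ± 0.09). Of 29 actomyosin genes 27 rose and none fell (adjusted p = 1.72e-17, adjusted p = 0.1 with an estimated correlation). TPM1 stood at 0.93 ± 0.04, TAGLN at 0.95 ± 0.04 and CALD1 at 0.90 ± 0.04. Of 27 actin nucleation genes 20 rose and 5 fell (adjusted p = 0.00107, adjusted p = 0.082 with an estimated correlation). ENAH stood at 0.87 ± 0.04 and the Arp2/3 subunit gene ARPC5 at 0.55 ± 0.04. Of the MRCK genes CDC42BPA rose (0.50 ± 0.04, adjusted p = 2.43e-12), CDC42BPB rose (0.28 ± 0.04, adjusted p = 2.81e-07) and CDC42BPG, much the lowest of them at 6.69 CPM in controls, fell (-1.46 ± 0.17, adjusted p = 2.39e-09). MYLK rose too (0.91 ± 0.04). Cadherins and protocadherins rose, 11 up and 2 down of 18 (adjusted p = 3.62e-05, adjusted p = 0.14 with an estimated correlation), with CDH11 at 1.5 ± 0.04 and CDH2 at 0.98 ± 0.04.

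YAP and TAZ targets rose, 17 up and 2 down of 21 (adjusted p = 9.71e-08, adjusted p = 0.25 with an estimated correlation), with CCDC80 at 1.18 ± 0.04 and MYOF at 0.82 ± 0.04. TGF-beta targets rose, 13 up and 5 down of 19 (adjusted p = 0.014, adjusted p = 0.29 with an estimated correlation). The matrix protein gene TGFBI rose (1.37 ± 0.04) and ID2 fell (-0.88 ± 0.04). NF-kB and inflammatory mediators rose, 11 of 18 up (adjusted p = 0.0189, adjusted p = 0.28 with an estimated correlation), with the chemokine gene CCL2 at 1.36 ± 0.08 and VCAM1 at 2.02 ± 0.14. Lysosome and autophagy genes rose, 21 up and 2 down of 27 (adjusted p = 1.36e-05, adjusted p = 0.14 with an estimated correlation), with HEXA at 0.71 ± 0.05 and CTSB at 0.53 ± 0.04. P53 targets rose, 17 up and 5 down of 28 (adjusted p = 0.0189, adjusted p = 0.3 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 0.64 ± 0.04. The mitochondrially encoded genes rose, 11 of 13 up (adjusted p = 0.000587, adjusted p = 0.38 with an estimated correlation), with MT-CYB at 0.57 ± 0.09. Fibroblast and smooth muscle markers rose, 8 up and 1 down of 9 (adjusted p = 7.88e-12, adjusted p = 0.082 with an estimated correlation). Decorin, DCN, stood at 1.11 ± 0.04 and COL1A1 at 1.13 ± 0.05. Of the 12 members of that marker list 6 are also in the matrix, collagen or actomyosin lists, and both controls and knockdown cells expressed COL1A1 strongly, at 4446 and 9721 CPM.

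DNA replication genes fell in 29 of 30 cases (adjusted p = 4.25e-09, adjusted p = 0.082 with an estimated correlation). The helicase subunit genes MCM3 and MCM4 stood at -0.70 ± 0.04 and -0.59 ± 0.04. Mitosis genes fell, 18 down and 1 up of 32 (adjusted p = 0.0281, adjusted p = 0.33 with an estimated correlation), with UBE2C at -0.38 ± 0.05. Cytosolic ribosomal proteins fell in 47 of 48 cases (adjusted p = 5.24e-10, adjusted p = 0.1 with an estimated correlation), with RPS7 at -0.66 ± 0.04. The 8p23.1 list passed with FAM167A among its members (adjusted p = 0.00107, adjusted p = 0.082 with an estimated correlation) and did not pass without it (6 down and 3 up of 14, adjusted p = 0.459), with GATA4 (-1.23 ± 0.07) and SOX7 (-1.88 ± 0.22) down and CTSB up. Not called were immediate early genes (6 up and 9 down of 21, adjusted p = 0.564), in which EGR1 fell (-1.02 ± 0.06) and IER3 rose (2.22 ± 0.16). Interferon response genes were not called either (22 up and 5 down of 34, adjusted p = 0.0801); OAS3 fell (-2.03 ± 0.09) and IFITM3 rose (0.69 ± 0.05). The same holds for antigen presentation (7 up and 1 down of 15, adjusted p = 0.0619, or 0.0497 without knockdown library 2 of SK-N-SH CRISPRi). Also not called were sterol synthesis (3 up and 11 down of 26, adjusted p = 0.0933), the stress and unfolded protein response (15 up and 5 down of 31, adjusted p = 0.108), and heat shock (3 up and 9 down of 19, adjusted p = 0.505). Neither were hypoxia and glycolysis (10 up and 10 down of 34, median 0.04, mean -0.04, adjusted p = 0.505) and nuclear oxidative phosphorylation (7 up and 9 down of 37, adjusted p = 0.853). Epithelial markers were not called (3 up and 1 down of 6, adjusted p = 0.0687, or 0.0414 under a filter at 1 CPM), and the Schwann cell, endothelial and blood lists had 4, 4 and 1 tested members, under the minimum of 5.

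Adjusted over the list alone, 646 list members passed in place of 634 adjusted over all genes (a gene counts in each of its lists), and the counts were equal in 23 of the 34 lists; mitosis genes then had 21 down, YAP and TAZ targets 18 up and mitochondrially encoded genes 13 up. In all 21 of 31 lists were called by camera, 15 up and 6 down, and 0 with an estimated correlation between genes (27 by fry), when the smallest adjusted p was 0.059. The 10 splits of the 6 libraries into equal groups are too few to test the counts of genes and lists against chance.

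The SK-N-AS CRISPRi experiment asks whether a second line responds in the same way. Inflammatory mediators, TGF-beta targets and matrix genes rose and adrenergic genes fell as lists, also with an estimated correlation (adjusted p = 0.001, 0.0015, 0.012 and 0.0018). IL1B, the cytokine interleukin-1 beta, rose 4.29-fold from 22.3 ± 0.786 to 95.3 ± 4.38 CPM (n = 4 in each group, adjusted p = 1.27e-29), and MMP1 rose 5.88-fold from 2.34 ± 0.399 to 14.2 ± 0.893 CPM. CHGB, a granin of catecholamine vesicles, fell 3.62-fold from 106 ± 5.2 to 29.3 ± 1.91 CPM. Of 19277 genes tested, 5904 (30.6%) changed, 2923 upward and 2981 downward, and 576 of them at least 2-fold, 366 upward and 210 downward.

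LAMP5 (-6.55 ± 0.07) and TEAD3 (-4.47 ± 0.10) fell further than FAM167A. The other leading falls were the kinase gene VRK2 (-2.16 ± 0.08), GCG, which encodes glucagon (-2 ± 0.03), VSTM4 (-1.93 ± 0.11), elastin, ELN (-1.90 ± 0.08), and MYO16 (-1.90 ± 0.15). Besides MMP1, the leading rises were the neuronal pentraxin NPTX1 (3.10 ± 0.16), LINC01915 (3.00 ± 0.12), SLC7A14 (2.50 ± 0.12), the hyaluronan-binding protein gene CEMIP (2.42 ± 0.04), the DNA sensor AIM2 (2.37 ± 0.14), ZNF667 (2.34 ± 0.14) and thrombomodulin, THBD (2.27 ± 0.10).

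Of 26 NF-kB and inflammatory mediators 22 rose and none fell, with a median of 0.59 (adjusted p = 1.09e-37, and 0.001 with an estimated correlation, also an adjusted p). CXCL12 stood at 1.90 ± 0.05, CXCL8 at 1.57 ± 0.07 and the mitochondrial superoxide dismutase gene SOD2 at 1.22 ± 0.03. Of 19 TGF-beta targets 15 rose and 1 fell (adjusted p = 3.05e-16, and adjusted p = 0.0015 with an estimated correlation). The inhibitory SMAD gene SMAD6 stood at 1.10 ± 0.04 and SMAD7 at 0.95 ± 0.04. Of 21 YAP and TAZ targets 12 rose and 3 fell (adjusted p = 1.06e-10, and adjusted p = 0.0021 with an estimated correlation), with IGFBP3 at 1.32 ± 0.05. Of 30 integrin and focal adhesion genes 17 rose and 4 fell (adjusted p = 1.03e-12, and adjusted p = 0.0017 with an estimated correlation). ITGB3 stood at 1.59 ± 0.07 and ITGA11 at 1.02 ± 0.03. Of 37 matrix glycoproteins and proteases 21 rose and 8 fell (adjusted p = 1.82e-10, and adjusted p = 0.012 with an estimated correlation). SPARC stood at 0.66 ± 0.02 and THBS1 at 0.71 ± 0.03. Collagens were 11 up and 4 down of 18 without a call (adjusted p = 0.0508), and the basement membrane chains COL4A1 (-1.60 ± 0.06) and COL4A2 (-1.52 ± 0.06) fell while COL3A1 rose (0.47 ± 0.02). In SK-N-AS CRISPRi the collagen list passed without knockdown library 1, 3 or 4 (adjusted p = 0.0464, 0.0453 and 0.0308) or control library 1 or 4 (0.0125 and 0.0474).

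Of 24 adrenergic identity genes 17 fell and 1 rose, with a median of -0.44 (adjusted p = 1.73e-25, and adjusted p = 0.0018 with an estimated correlation). RET stood at -0.85 ± 0.02, the transcription factor gene TFAP2B at -0.85 ± 0.03 and the noradrenaline transporter gene SLC6A2 at -1.26 ± 0.06. Of 26 mesenchymal identity genes 18 rose and 4 fell (adjusted p = 2.82e-05, and adjusted p = 0.017 with an estimated correlation). RUNX1 (0.89 ± 0.06) and FOSL2 (0.45 ± 0.03) rose, and SOX9 (-0.75 ± 0.04) and TWIST1 (-0.77 ± 0.04) fell. Neurite genes rose as a list, 12 up and 7 down of 26 (adjusted p = 0.0135, adjusted p = 0.065 with an estimated correlation). The neurofilament genes NEFL (1.33 ± 0.04) and NEFM (1.09 ± 0.04) rose, while the synaptic vesicle gene SYP fell (-0.98 ± 0.07). Axon guidance genes, 12 up and 13 down of 34, were not called (adjusted p = 0.333), with NRP1 at 0.79 ± 0.03 and SEMA3F at -1.66 ± 0.09. Cadherins (7 up and 2 down of 18, adjusted p = 0.355), with PCDH18 at -0.51 ± 0.04, were not called.

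The actomyosin list had 12 up and 8 down of 27 and was not called (adjusted p = 0.0668), with TPM1 at 1.08 ± 0.03, TPM2 at 0.90 ± 0.05 and MYH9, the non-muscle myosin IIA heavy chain, at 0.38 ± 0.03, while CNN3 fell (-0.57 ± 0.03). It passed without knockdown library 3 or 4 or control library 1 of SK-N-AS CRISPRi (adjusted p = 0.0451, 0.0416 and 0.0376). Actin nucleation genes, 10 up and 2 down of 27 (adjusted p = 0.262), included MYO10 at 1.08 ± 0.07 and fascin, FSCN1, at -0.33 ± 0.03. MYLK stood at 0.23 ± 0.04 and PPP1R12B at -0.27 ± 0.04. None of the MRCK genes passed, CDC42BPA at 0.07 ± 0.03 (adjusted p = 0.0692), CDC42BPB at -0.05 ± 0.03 (adjusted p = 0.186) and CDC42BPG at -0.53 ± 0.29 (adjusted p = 0.185). CDC42BPA passed without knockdown library 2 or control library 3 (adjusted p = 0.0423 and 0.0157), under a filter at 1 CPM (0.0324) and with a replicate block (0.0422).

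Lysosome and autophagy genes rose, 21 up and 3 down of 28 (adjusted p = 3.21e-07, and adjusted p = 0.012 with an estimated correlation). CTSB stood at 0.50 ± 0.03 and LAMP1 at 0.37 ± 0.03. Stress and unfolded protein response genes rose, 17 up and 4 down of 31 (adjusted p = 8.03e-05, and adjusted p = 0.012 with an estimated correlation), with the amino acid transporter gene SLC7A5 at 0.73 ± 0.05. DNA replication genes fell in 22 of 30 cases with none up (adjusted p = 4.56e-06, and adjusted p = 0.011 with an estimated correlation). E2F1 stood at -0.41 ± 0.04 and MCM2 at -0.26 ± 0.03. The next lists were called with the preset correlation alone. Immediate early genes rose, 13 up and 4 down of 24, with KLF4 at 0.97 ± 0.07 (adjusted p = 0.00906, adjusted p = 0.48 with an estimated correlation). Antigen presentation genes rose in 10 of 19 cases, with HLA-B at 0.45 ± 0.03 (adjusted p = 0.00151, adjusted p = 0.069 with an estimated correlation). Hypoxia and glycolysis genes rose, 12 up and 4 down of 34, with EGLN3 at 0.98 ± 0.04 (adjusted p = 0.00108, adjusted p = 0.095 with an estimated correlation). Sterol synthesis genes fell, 12 down and 1 up of 26, with SREBF1 at -0.45 ± 0.04 (adjusted p = 0.00108, adjusted p = 0.12 with an estimated correlation). Ribosomal proteins fell in 38 of 48 cases, with RPL8 at -0.21 ± 0.03 (adjusted p = 1.72e-05, adjusted p = 0.3 with an estimated correlation). Fibroblast and smooth muscle markers rose, 6 up and 3 down of 9, with PDGFRA at 0.83 ± 0.03 and COL1A1 at -0.52 ± 0.03 (adjusted p = 0.00807, adjusted p = 0.065 with an estimated correlation).

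Not called in SK-N-AS were p53 targets (6 up and 8 down of 28, median -0.01, mean 0.05, adjusted p = 0.821), in which CDKN1A rose (0.93 ± 0.05). Neither were mitosis (1 up and 6 down of 32, adjusted p = 0.333), interferon response (11 up and 4 down of 39, adjusted p = 0.216), heat shock (3 up and 6 down of 19, adjusted p = 0.333), nuclear oxidative phosphorylation (1 up and 8 down of 38, adjusted p = 0.314) and mitochondrially encoded genes (1 up and 3 down of 13, adjusted p = 0.52). The 8p23.1 list without FAM167A had 5 up and 2 down of 14 and an adjusted p of 0.193 (0.0508 with FAM167A among its members). Epithelial (3 up and 2 down of 8, adjusted p = 0.769), endothelial (1 of 5 up, adjusted p = 0.333) and blood markers (1 up and 2 down of 5, adjusted p = 0.797) were not called, and of 4 tested Schwann cell and glia markers 1 rose and 2 fell.

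In all 17 of 33 lists were called, 13 up and 4 down, and 10 with an estimated correlation, 8 up and 2 down (27 by fry). Other splits of the 8 libraries called up to 19 lists, so chance was not excluded for the number of lists. Adjusted over the list alone, 529 list members passed in place of 505 adjusted over all genes (a gene counts in each of its lists), and the counts were equal in 16 of the 34 lists; the mesenchymal list then had 19 up and ribosomal proteins 40 down. Blood markers had a median of -0.27 and a mean of 0.13.

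**Figure D2:**
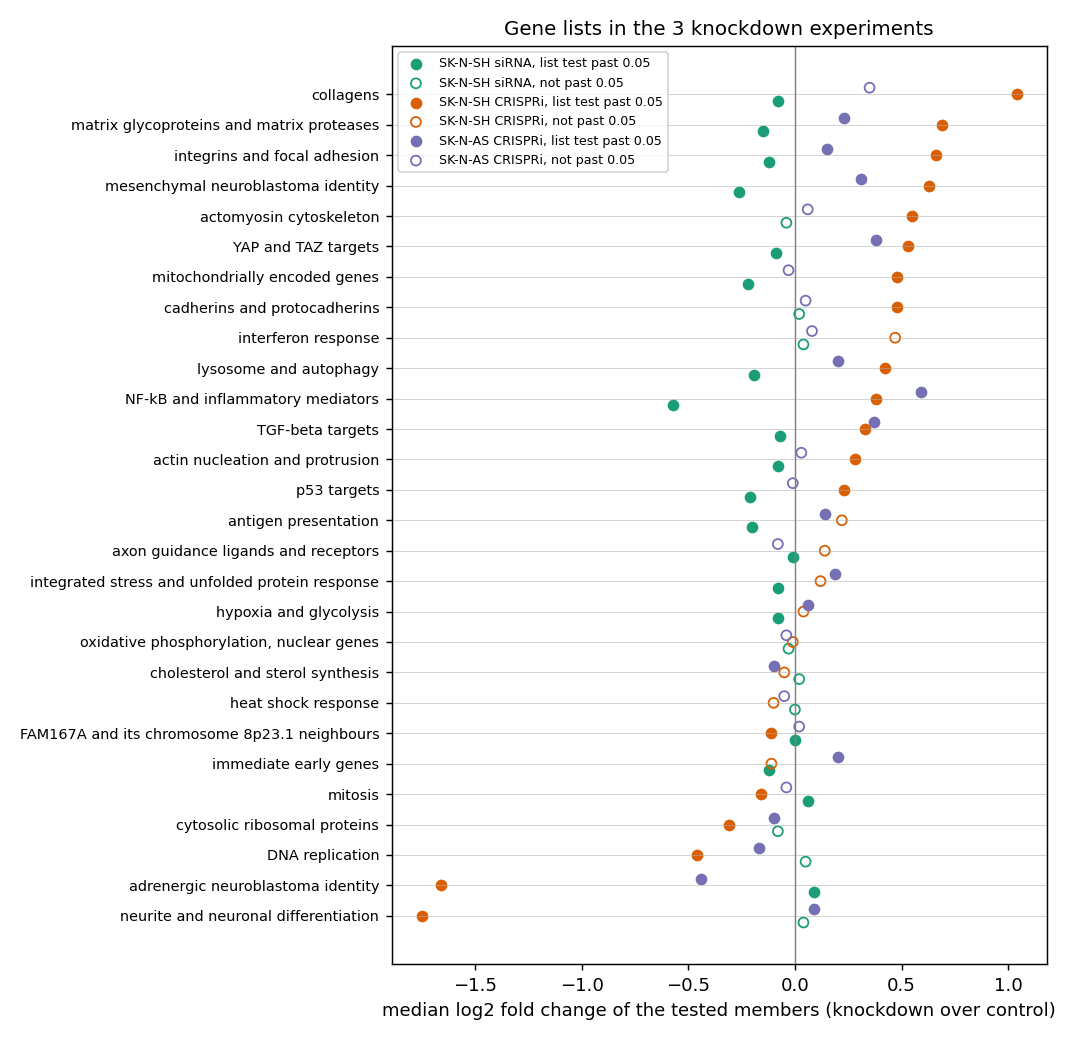
Median log2 fold change, knockdown over control, of the tested members of pathway lists in the 3 experiments; filled points mark lists with an adjusted p under 0.05 in camera with the preset correlation. The adrenergic list lies at -1.66 in SK-N-SH CRISPRi, -0.44 in SK-N-AS CRISPRi and 0.09 with siRNA, and the collagens at 1.04, 0.35 and -0.08.

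Comparing the experiments asks which changes go with the loss of FAM167A whatever the method or line. The CRISPRi experiments moved many genes the same way, and many genes that fell with siRNA rose with CRISPRi, as in the plot of shared calls. Both CRISPRi experiments carry the same guide label. Effects of the guide beyond FAM167A that they share cannot be told apart here from effects of its loss. Between SK-N-SH and SK-N-AS CRISPRi, 2851 of 14236 genes tested in both were called in one direction (1388 up and 1463 down, against 1430 for independent lists) and 809 in opposite directions (1430 for independent lists). Log2 fold changes had r = 0.274 and rho = 0.325 across genes, which are not independent replicates. Between siRNA and CRISPRi in SK-N-SH, 305 of 14973 genes were called in one direction (159 up and 146 down, against 139 and 393) and 1098 in opposite directions (528), with r = -0.223 and rho = -0.237. Of the opposite calls 919 fell with siRNA and rose with CRISPRi (387 for independent lists) and 179 went the other way (141). Leaving out control library 2 of the siRNA experiment took the 305 to 199 and the 159 rises to 100. Between siRNA and SK-N-AS CRISPRi, 299 of 16113 genes were called in one direction (102 up and 197 down, against 78.2 and 240) and 702 in opposite directions, 593 of them down with siRNA (219) and 109 up with siRNA (85.6), with r = -0.115 and rho = -0.0916.

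**Figure D3:**
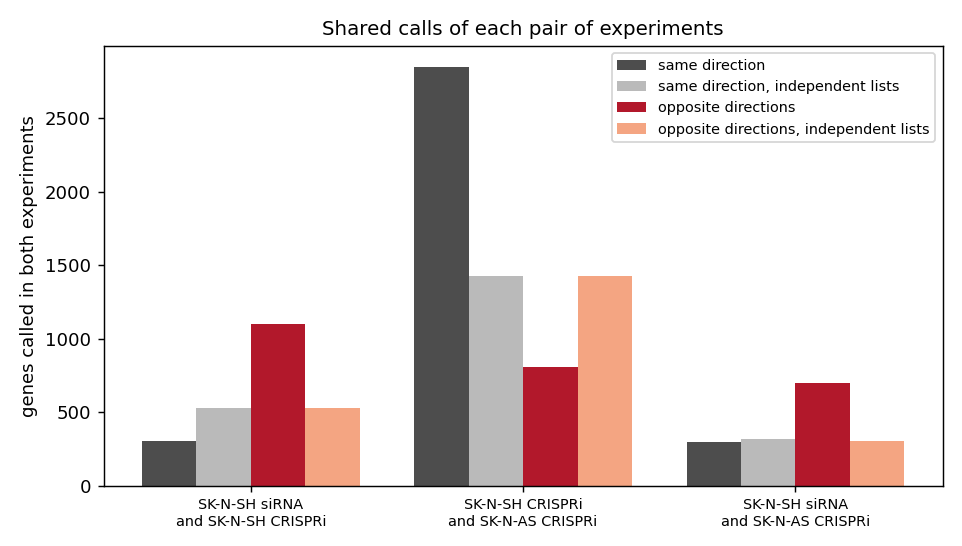
Number of genes called in both experiments of each pair, in the same and in opposite directions, beside the numbers for independent lists of the same sizes. Opposite calls reach 1098 for siRNA and CRISPRi in SK-N-SH against 528 for independent lists, and same-direction calls reach 2851 for both CRISPRi experiments against 1430.

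Single genes and lists differed as well. PLAT fell with siRNA and rose with CRISPRi in SK-N-SH, a difference of -2.59 ± 0.08 (log2, siRNA minus CRISPRi, adjusted p = 2.4e-23), and ITGA2 did likewise, by -3.1 ± 0.09 (adjusted p = 5.2e-23). RET rose with siRNA and fell with CRISPRi, a difference of 2.54 ± 0.07 (adjusted p = 1.1e-23). In a model over both SK-N-SH experiments 7317 of 23287 genes (31.4%) responded differently, 3811 with the siRNA value higher and 3506 with it lower. The model holds a single spread per gene, although the common coefficient of variation was 0.0857 with siRNA and 0.0377 in SK-N-SH CRISPRi. Its p-values and SEs may therefore misstate the spread of either experiment. It also holds genes beyond the 14973 tested in both. Of 34 lists 23 differed, 13 of them with an estimated correlation, led by the adrenergic list (adjusted p = 1.17e-63, and adjusted p = 7.7e-05 with an estimated correlation), higher with siRNA. Collagens (adjusted p = 0.021 with an estimated correlation), actomyosin genes (0.014), integrins (0.011) and mesenchymal genes (0.012) lay lower with siRNA. Between the CRISPRi experiments 6098 of 19862 genes (30.7%) responded differently, 3178 with the SK-N-SH value higher and 2920 with it lower. COL4A1 rose in SK-N-SH and fell in SK-N-AS, a difference of 2.75 ± 0.06 (adjusted p = 3e-34), and so did COL4A2 (2.56 ± 0.06, adjusted p = 3.4e-33). Of 34 lists 18 differed, 8 of them with an estimated correlation, among them adrenergic genes (adjusted p = 0.022 with an estimated correlation) and neurite genes (0.022), both lower in SK-N-SH.

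Across all 3 experiments 110 of 13943 genes tested in each were called in one direction, 63 up and 47 down, against 94.2 for independent lists. With 22.9 up and 71.3 down for independent lists, the rises exceeded that number and the falls did not reach it, and 796 genes were called in all 3 experiments in any direction. These numbers take all 3 lists as independent, but the CRISPRi lists shared 2851 calls of one direction against 1430. The excess of rises is therefore no measure of agreement between siRNA and CRISPRi. The 47 falls were 31 without control library 2 of the siRNA experiment. Genes that rose in all 3 include MEST (0.94 ± 0.07, 0.75 ± 0.04 and 0.51 ± 0.04 with siRNA, SK-N-SH CRISPRi and SK-N-AS CRISPRi), the endothelial and cardiac surface protein gene HEG1 (0.57 ± 0.05, 0.44 ± 0.05 and 0.61 ± 0.03), tropomyosin 1, TPM1 (0.23 ± 0.04, 0.93 ± 0.04 and 1.08 ± 0.03), and the focal adhesion gene TNS3 (0.32 ± 0.05, 1.20 ± 0.05 and 0.45 ± 0.04). ALPK2, the cytokine receptor gene LIFR, LRRC17, FHIP2A, NNMT, the LIM-domain gene AJUBA and the protease gene ADAMTS15 rose as well. The receptor tyrosine kinase gene MET fell in all 3 (-0.34 ± 0.05, -0.35 ± 0.04 and -0.95 ± 0.09), as did the fatty acid desaturase gene FADS2 (-0.30 ± 0.04, -0.36 ± 0.04 and -0.28 ± 0.02), KLHDC3 (-0.39 ± 0.05, -0.38 ± 0.04 and -0.23 ± 0.03) and FAM167A.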

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

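Chosen only after the result was seen were the tests of libraries that stand apart, of the differences of gene lists, of TEAD3 and LAMP5, of the adrenergic and mesenchymal genes, and the first search for seed heptamers; the splits of the libraries, the search of FAM167A for the octamer and the correlation without heptamer genes were set down before their results.

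Responses differed between the SK-N-SH experiments for 7317 of 23287 genes and 23 of 34 lists, and between the CRISPRi experiments for 6098 of 19862 genes and 18 of 34 lists. Each count comes from a test of the difference itself, with a single spread per gene over both experiments. Between siRNA and CRISPRi in SK-N-SH the differences in log2 fold change with the smallest p were RET (2.54), MFAP5 (-3.5), NPR3 (-2.65), PLAT (-2.59), GATA2 (2.19), ITGA2 (-3.1), GNG4 (2.18) and FAM167A (4.72). Between CRISPRi in SK-N-SH and SK-N-AS they were COL4A1 (2.75), BGN (3.24), COL4A2 (2.56), CD63 (-2.25), ADAMTS9 (-1.98), DPYSL3 (1.75), IGFBP2 (2.35) and PLAT (1.91). With an estimated correlation 13 and 8 lists differed.

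Some libraries lay far from the rest of their group on principal components of log2 CPM or in the share of reads from long non-coding RNA genes. Knockdown library 4 of the siRNA experiment lay at -14.6 on the second component and the others of its group between 14.8 and 18.7. Control library 5 of that experiment lay at -15 on the first component, the others between 23 and 28.2, and long non-coding RNA genes took 1.26% of its reads against 1.124 to 1.158%. In SK-N-AS CRISPRi, control library 2 lay at 44.8 on the first component, the others between 22.1 and 23.9, and at 42.6 on the second, the others between -23.7 and -14.3. Of 32 tests of a group and quantity 5 passed, where chance gives about 1 in 20. The nuclear RNAs NEAT1 and KCNQ1OT1 were higher by 0.62 and 0.52 (log2) in siRNA knockdown library 4, and by 0.79 and 1 in control library 5, than in the rest of their groups; these genes were chosen after their values were seen. Knockdown libraries 3 and 4 differed less from each other (chi-square per gene 7.85) than from the other knockdown libraries (27.3 to 44.6). The residuals of knockdown library 4 and control library 5 correlated at 0.3.

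Other splits of the libraries make chance unlikely for the number of genes changed with siRNA (2004, highest other 83, 100 splits with the real one). The same holds in SK-N-AS CRISPRi (5904, highest other 0, 35 splits with the real one). Whether replicates are separate cultures is not given, so splits do not reach chance differences between cultures. For the number of lists with siRNA the splits make chance unlikely but do not exclude it, since another split reached more (19, highest other 20). With the real split counted, 2 of 100 splits gave as many. Chance is not excluded either for the lists in SK-N-AS CRISPRi (17, highest other 19). For SK-N-SH CRISPRi the 10 splits are too few (8582 genes, highest other 0; 21 lists, highest other 21). Regroupings decide nothing about shared calls of one direction, since most of them call no gene in at least 1 experiment: between siRNA and CRISPRi in SK-N-SH (305, highest other 23), between the CRISPRi experiments (2851, highest other 0), between siRNA and SK-N-AS CRISPRi (299, highest other 21) and in all 3 experiments (110, highest other 0). For r, in the same order of pairs, the regroupings make chance unlikely but do not exclude it, since the margins are narrow. The values were -0.223 (highest other -0.218), 0.274 (0.235) and -0.115 (-0.115, where 2 of 100 gave as much). Genes whose response differed numbered 7317 (highest other 5967) and 6098 (highest other 4853). Regrouping breaks up the knockdown effects along with any difference between them, so these counts cannot tell whether the responses were equal.

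TEAD3 and LAMP5 fell at least 8-fold in both CRISPRi experiments, as FAM167A did, and the next shared fall was SMPD3, at -2.07. The tables argue against a response in proportion to the loss of FAM167A: scaled by FAM167A, the SK-N-AS falls give -2.12 for TEAD3 and -3.1 for LAMP5 with siRNA, and the SK-N-SH fall gives -0.87 for LAMP5, where the values were -0.15 (95% interval -0.31 to 0) and -0.03 (-0.15 to 0.09). Repression by the CRISPRi guide at sites other than FAM167A is a candidate explanation, and the siRNA values of -0.15 and -0.03 are in line with it. The guide sequence was not used here. Tested genes within 200 kb moved less in SK-N-SH and SK-N-AS. Near TEAD3 the lowest values were those of FANCE, at -0.49 and -0.26. RPL10A, which lies between FANCE and TEAD3, stood at -0.33 and -0.14, and PLCB4 near LAMP5 at -0.61 and -0.53. These values do not tell whether the guide acts at TEAD3 or LAMP5 (SMPD3, FANCE, RPL10A and PLCB4 were chosen after their values were seen). A response that needs a loss of FAM167A deeper than the siRNA gave stays open.

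The siRNA and CRISPRi experiments in SK-N-SH moved genes in opposite directions, with r = -0.223, and 919 of 1098 opposite calls fell with siRNA and rose with CRISPRi. In the siRNA experiment genes with the heptamer GGGAGCT in their 3′ untranslated region were lower (t = -9.74), then GGAGCTA (t = -9.37), while the next heptamer not overlapping these had t = -5.54 and the lowest in the CRISPRi experiments were -5.48 and -4.94. The octamer GGGAGCTA that joins them occurs in the 3′ untranslated region of FAM167A (chromosome 8, 11423858 to 11423865, exon 3 of 3 of its longest transcript). It also occurs in 4.94% of 12113 coding transcripts of like length. An siRNA against FAM167A that may also lower genes by seed matches is a candidate explanation. Of 233 genes with the octamer 30% fell, of 1710 with a heptamer alone 17.5%, and of 10047 with neither 9.15%. The heptamers were picked as the lowest in these same data, so such a gradient was built in and gives no further support. These shares were not adjusted for the length of the untranslated region. The tables argue against direct matches to these 2 heptamers in the searched regions as the whole cause of the negative correlation. Over 10577 genes without either heptamer r was -0.238. The tables also argue against knockdown library 4 and control library 5, without which r was -0.237. Leaving out genes with a heptamer does not reach matches outside the searched regions, or genes that changed in turn, so both stay open. Seed matches of the other siRNAs of the pool or of the non-targeting pool, other effects of the siRNAs, and effects of the guide beyond FAM167A, of the depth of knockdown and of a different starting state of the cultures, whose controls held TAGLN at 13.9 (siRNA) and 893 CPM (CRISPRi), stay open.

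In SK-N-SH CRISPRi adrenergic genes fell (median -1.66) and mesenchymal genes rose (median 0.63). The tables argue against a response in proportion to the loss of FAM167A that both methods share: scaled by FAM167A, the adrenergic median would be -0.41 with siRNA, and it was 0.09 (SD of members 0.12), with 24 of 25 members above their scaled value. Adrenergic genes fell in SK-N-AS CRISPRi too, by less (median -0.44, camera adjusted p = 0.0018 with an estimated correlation). Neurite genes had a median of -1.75 in SK-N-SH CRISPRi and 0.09 in SK-N-AS CRISPRi. A fall in another line cannot tell whether the mixture of cells changed in the SK-N-SH cultures. A different share of neuroblast-like and substrate-adherent cells in knockdown and control cultures and a change within the cells cannot be told apart, because bulk libraries hold both and the median of -1.66 is what either could give. A response that needs a deeper loss of FAM167A than the siRNA gave stays open too.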

How the results depend on the processing

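Leaving out both siRNA libraries that stand apart and the separate fits for differences between experiments were chosen after the data were seen. The direction of FAM167A and its side of the threshold held in all settings run, with log2 fold changes without 1 library from -1.567 to -1.488 (siRNA), -6.367 to -6.099 (SK-N-SH CRISPRi) and -3.259 to -3.178 (SK-N-AS CRISPRi). No call of a named gene reversed. A fold threshold left 147, 1658 and 576 genes, by its construction. Camera with an estimated correlation called 0, 0 and 10 lists, and fry, which does not compare a list with other genes, called 27 in SK-N-AS CRISPRi. Across the alternative scalings, models and filters the number of genes ranged from 1532 (replicate block) to 2444 (DESeq2) with siRNA, from 7363 (DESeq2) to 8574 in SK-N-SH CRISPRi and from 5485 (no filter) to 5989 (limma-voom) in SK-N-AS CRISPRi. The correlation of siRNA with SK-N-SH CRISPRi was -0.237 by Spearman's rho and -0.237 without both libraries that stand apart. That between the CRISPRi experiments was 0.334 under a filter at 1 CPM and 0.325 by rho. That of siRNA with SK-N-AS CRISPRi was -0.167 under that filter, -0.122 without both libraries and -0.092 by rho. Outside the alternatives' own construction, the cause was not tested. Without each library in turn the genes changed ranged from 1406 (without siRNA control 4) to 2515 (without siRNA control 5), 7776 to 8449 and 5149 to 5900, and the lists from 19 to 22, 21 to 22 and 17 to 20. Shared calls of one direction ranged from 199 to 354 (siRNA and SK-N-SH CRISPRi), 2530 to 2824 (both CRISPRi) and 211 to 343 (siRNA and SK-N-AS CRISPRi), with r from -0.235 to -0.201, 0.26 to 0.274 and -0.124 to -0.1. Calls in all 3 experiments ranged from 75 to 126, and genes whose response differed from 6418 to 7483 and 5396 to 6097. The low values of 199, 211 and 75 are without siRNA control library 2. Over the genes named and the settings run, 7005 of 7106 values kept their side of the threshold, 73 lost a call and 28 gained one. Most named genes were chosen in these same data for a small adjusted p or a large fold, which favours such stability. Of 423 called results for these genes 19 lost their call in some setting, and 18 did so with a library left out. Direction was compared only where the main fit or the alternative called the gene. At the depths here simulated 2-fold changes were called for 80 to 90% of genes, so some changes are missed.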

Other observations

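Controls of the SK-N-SH experiments differed in level for genes of the smooth muscle and matrix lists; no test was made, since library kits and tables differ. TAGLN stood at 13.9 ± 0.778 CPM in siRNA controls and 893 ± 46.2 in CRISPRi controls, ACTA2 at 17.7 ± 1.82 and 458 ± 33.7, DCN at 2.82 ± 0.34 and 109 ± 4.89, and LUM at 19.9 ± 0.783 and 343 ± 13.2. RET was closer, at 451 ± 24.1 and 348 ± 7.74 CPM. In SK-N-AS controls COL1A1 stood at 900.4 ± 43.9 CPM and COL3A1 at 1551 ± 25.1.

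Some markers of other cell types were expressed. PTPRC, which encodes the leukocyte surface phosphatase CD45, stood in SK-N-AS at 542 ± 19.1 CPM in controls and 451 ± 14.1 in knockdown (log2 fold change -0.27 ± 0.03, adjusted p = 5.9e-10), while the leukocyte actin-bundling gene LCP1 rose from 0.945 ± 0.206 to 2.52 ± 0.242 CPM and CORO1A fell from 4.73 ± 0.415 to 3.73 ± 0.36 CPM. NGFR, the low-affinity neurotrophin receptor, fell in SK-N-SH CRISPRi from 15.2 ± 1.21 to 3.14 ± 0.345 CPM, and KRT18, a keratin of simple epithelia, rose from 73.2 ± 2.49 to 140.3 ± 2.85 CPM. With siRNA the endothelial genes PECAM1 and ROBO4 fell at low levels, from 0.685 to 0.203 and from 1.24 to 0.543 CPM. Of the marker lists, 1 of 12 Schwann cell genes, 1 of 14 epithelial genes, 0 of 10 endothelial genes, 0 of 12 blood genes and 6 of 12 fibroblast and smooth muscle genes are also in another list.

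CD63, a tetraspanin of late endosomes and exosomes, fell in all 3 experiments, to 12.7% of control in SK-N-SH CRISPRi (log2 fold change -2.97 ± 0.05), 61.4% in SK-N-AS CRISPRi (-0.70 ± 0.02) and 78% with siRNA (-0.36 ± 0.07, adjusted p = 0.00431). The antisense gene CD63-AS1, which overlaps its start on chromosome 12 (55729094 to 55730857 in the SK-N-SH CRISPRi table), had 0 reads in SK-N-SH CRISPRi knockdown against 190 in control, fell in SK-N-AS CRISPRi (-1.13 ± 0.12, adjusted p = 7.26e-10) and did not pass with siRNA (-0.06 ± 0.11, adjusted p = 0.81). Near it ITGA7 fell in SK-N-SH CRISPRi (-1.29, adjusted p = 7.3e-07) and stood at -0.16 in SK-N-AS CRISPRi (adjusted p = 0.031). Other genes there went both ways. MMP19 rose in SK-N-SH and SK-N-AS CRISPRi (0.67, adjusted p = 0.0043, and 1.01, adjusted p = 0.00032). DGKA rose in SK-N-SH CRISPRi (0.66, adjusted p = 8.5e-13) and stood at -0.07 in SK-N-AS CRISPRi (adjusted p = 0.43). GDF11 fell in both (-0.18, adjusted p = 0.013, and -0.29, adjusted p = 1.7e-09). Within 200 kb of FAM167A, the antisense transcript TDH-AS1 stood at -1.9 in SK-N-SH CRISPRi (adjusted p = 0.0015) and -0.02 in SK-N-AS CRISPRi (adjusted p = 0.94), and MTMR9 at 0.17 (adjusted p = 0.018) and 0 (adjusted p = 0.97). ENSG00000269954, a gene without a symbol there, stood at -0.5 (adjusted p = 2e-07) and 0.94 (adjusted p = 4.5e-11). ITGA7, MMP19, DGKA, GDF11 and these 3 neighbours of FAM167A were chosen after their values were seen.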
